A study of Mus musculus with 34 samples.

How the data were processed

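The series holds 34 samples, 2 of them of a plasmid library and the others of mouse splenic B cells from the CD43-negative fraction, obtained by magnetic selection against CD43, a surface protein that most resting B cells lack. Activated cells were cultured with lipopolysaccharide (LPS, a bacterial cell wall component that activates B cells through a Toll-like receptor) at 10 µg per ml for 3 days, and resting B cells were the control. The growth and treatment fields of the resting samples repeat the LPS culture, so the labels do not settle how these cells were handled; they were grouped as resting by their titles and source names and the series design. RNA-seq was made from 2 activated and 2 resting samples. FAIRE-seq recovers nucleosome-poor DNA from crosslinked chromatin. STARR-seq places DNA fragments in a reporter plasmid so that a fragment with enhancer activity drives its own transcription. Per the series design, the plasmid library was made from FAIRE-seq DNA, and the reporter ran for 12 h or 24 h before RNA was taken. Hi-C, which records pairs of genome regions in contact, and ChIP-seq for H3K27ac, H3K4me3 and H3K4me1 were made from activated cells. The values of the H3K4me1, nascent RNA, plasmid library and resting ChIP-seq samples were not analysed here.

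The submitters' processing notes name Bowtie2, Bowtie, HOMER, bedtools, TopHat2 and STAR and the genome build mm9, with no role or version for each. The deposited RNA table holds 23812 gene rows with a symbol, a locus and 1 value per sample. Its unit is not named in the headers or labels, and the deposited values were treated as FPKM (fragments per kilobase of transcript, scaled to the mapped reads) because they are not whole numbers and their sums differ between samples. The deposited table gives no read totals, so the depth behind each RNA value is unknown. No strand is given, so that reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies or pseudogenes have uncertain values. In 27 rows the symbol had been turned into a date, and 265 symbols stood on more than 1 row. These rows stayed in the counts and were never named.

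Per the labels, 1 peak list was given for each of FAIRE-seq, STARR-seq, H3K27ac and H3K4me3, and lists of STARR peaks in FAIRE peaks and of super-enhancers (long domains of H3K27ac), which no sample label names, were used as well. The FAIRE and ChIP-seq lists are named under replicate 1 in the labels, and the STARR list under the 12 h and 24 h runs together. Replicates can therefore not be compared at the level of peaks, and differences between the STARR times were not tested. The lists give a chromosome, a start and an end, with no score. Duplicate rows were removed, and coordinates are printed 1-based on mm9. The deposited Hi-C list gives for each contact 2 anchors, a read count over pooled replicates, a z-score and the log of a p-value, none of which was used to filter further. The contact z-score and the count were kept as deposited by the authors.

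For RNA, genes with a value of at least 1 in at least 2 samples were tested with limma 3.58.1 (trend and robust options, R 4.3.3) on log2(FPKM + 1), without a block, and Benjamini-Hochberg adjusted p under 0.05 was called. A fold change is on this log2 scale and understates the change of low genes. Of the count tests in the plan, none applied to this unit. The 20 gene lists were fixed before the data were examined, as were the groups, the tests and the rule for named genes: 13 programmes, 6 lists of other cell types and 1 of mitochondrial transcripts. Of 253 members 242 were matched to a symbol in the table, 3 of them by an older symbol in a RefSeq table (GRCm38.p6, used for names only). Lists with at least 3 tested genes were tested with camera (inter-gene correlation 0.01) and fry. None of the 9 mitochondrial members was matched. The named genes were the 10 with the largest rise and the 10 with the largest fall among called genes with non-overlapping groups and a mean of at least 5 in the higher group, leaving out immunoglobulin and T cell receptor segments and predicted names, up to 4 called members per list with the largest change, and called members against the majority of their list. Some genes that this rule names are not reported here. For Hi-C they were the 10 genes with the most enhancers and list members with at least 5. For peaks they were the 5 super-enhancers with the most STARR peaks. The rule for the 5 STARR peaks with the highest score could not be used because the lists hold no score. Data for activated against resting cells were also simulated with 10540 genes, 100 of them changed 2-fold and 100 changed 4-fold. There limma called 30% of genes changed 2-fold and 71% of genes changed 4-fold, with 2 false calls among 103. Far fewer genes changed in the simulation than were called in the data, which makes the adjusted threshold stricter. The spreads were also shuffled across genes. These shares therefore do not give the recovery in the data.

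Peaks were compared by an overlap of at least 1 bp in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), with overlap counts checked against bedtools 2.31.1. The null for an overlap came from 1000 circular shifts of the STARR peaks within each chromosome (one-sided, smallest p 0.001). On simulated peak lists this test gave p under 0.05 in 1 of 20 lists without association and in 20 of 20 lists with 300 planted overlaps. Odds ratios were tested with Fisher's exact test (two-sided), and their 95% intervals, like those of all shares of peaks, came from 1000 bootstrap samples of chromosomes. These intervals cover differences between chromosomes of 1 list, not between replicates. A gene was linked to an enhancer when a Hi-C anchor overlapped an end of its locus that lay within 1 kb of an H3K4me3 peak and the other anchor overlapped a STARR peak in FAIRE. Both ends were used because the RNA table gives no strand. Permutation tests across genes used 100000 resamples (two-sided, smallest p 1e-05).

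Also tried were other filters, pseudocounts of 0.1 and 5, quantile normalization, the replicate number as a block, each replicate left out, other thresholds, other overlaps, other nulls and other sets of linked genes. The planned use of peak scores was replaced, after seeing the data, by the deposited order of the lists, whose meaning is not stated.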

Results

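The data compare B cells from mouse spleen after 3 days with LPS to resting B cells, and map the enhancers of the activated cells. The RNA table held 2 activated and 2 resting samples, whose FPKM values summed to 285068 and 285129 in the activated and 244602 and 287884 in the resting samples. Across tested genes the log2 values of replicates had a Pearson r of 0.981 in resting and 0.974 in activated cells, against 0.744 to 0.790 between the groups. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The peak lists held 55126 distinct FAIRE peaks, 17381 STARR peaks, 11808 STARR peaks in FAIRE, 23938 H3K27ac peaks, 16861 H3K4me3 peaks and 48 super-enhancers, and the Hi-C list held 27903 distinct contacts. There are no replicates for the peak lists or the contacts.

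The first comparison asks how the transcriptome differs between activated and resting B cells. In activated cells 14 of 15 tested plasma cell genes, all 18 of the unfolded protein response and secretion and all 24 of the cell cycle rose. So did all 13 of cholesterol synthesis and 14 of 15 of one-carbon, serine and nucleotide synthesis. In contrast, 17 of 19 genes of mature B cell identity and 14 of 17 of quiescence and homing fell. Camera called these 7 lists, and none was called with an estimated correlation (adjusted p = 0.342 to 0.388). That setting rests on the residual degrees of freedom of 2 against 2 samples, so it had little power for any list. Cholesterol synthesis lost its call in that setting although its estimated correlation was -0.0627. The estimated correlations of the other lists ran from 0.108 (quiescence) to 0.922 (cell cycle). These lie above the 0.01 preset in camera, so the camera p-values of those lists may be too small. The setting therefore cannot decide whether correlation between genes undoes the calls. Prdm1, which encodes the plasma cell regulator Blimp-1, rose from 1.25 ± 0.0254 to 68.6 ± 10.3 FPKM (SD, n = 2 per group; limma adjusted p = 1.58e-05). Cr2, the complement receptor of mature B cells, fell from 166.2 ± 11.4 to 9.36 ± 3.08 FPKM (limma adjusted p = 6.87e-05). Of 10863 genes tested with limma, 3066 were higher and 2844 lower in activated cells at a Benjamini-Hochberg adjusted p under 0.05, and 1525 and 1317 of these changed at least 2-fold. The groups did not overlap in 80.6% of tested genes, where chance gives 33.3% for 2 against 2. Called genes fell to 2964 without resting replicate 1 (1735 higher, 1229 lower) and 3324 without resting replicate 2 (2133 higher, 1191 lower), and in both cases 580 of the lower genes were no longer tested.

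The largest rise was that of Zbtb32, a transcriptional repressor of activated lymphocytes, from 1.33 ± 0.175 to 139.8 ± 12.4 FPKM, 60.3-fold on the scale of FPKM + 1. Asns, which makes asparagine, was 55.1-fold higher and Slc7a3, a carrier of cationic amino acids, 27.1-fold higher. Chac1, which degrades glutathione, rose from 0.103 ± 0.0308 to 30.8 ± 5.04 FPKM, and the cell cycle inhibitor gene Cdkn2a from 0.151 ± 0.00169 to 46.6 ± 3.08 FPKM. Tmed6, of a family of secretory pathway proteins, reached 66.1 ± 31.6 FPKM, the growth factor gene Vegfa 42.2 ± 2.97 FPKM and Fam46c, a poly(A) polymerase, 145.6 ± 7.68 FPKM. The adjusted p of these 8 genes in limma lay between 8.03e-06 and 0.000508. Among the 10 largest falls was Icosl, the ligand of the costimulator ICOS, from 142.2 ± 8.08 to 2.21 ± 0.952 FPKM. The small nucleolar RNA Snord8 had 72.7 and 69.0 FPKM in the resting samples and was listed at 0 in both activated samples. Values of such short genes are uncertain. Another of them, Snord47, was the highest gene of activated replicate 1 at 6492 FPKM, while no gene exceeded 2031 FPKM in activated replicate 2. The other 8 of the 10 largest falls were Beta-s, Hbb-b1, C1qa, C1qb, C1qc, Vcam1, Slc40a1 and Tyrobp, given with the markers of other cell types.

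All 24 cell cycle genes rose (camera adjusted p = 7.03e-11; adjusted p = 0.388 with an estimated correlation). Top2a, the topoisomerase of dividing cells, was 16.3-fold higher, Cdc20 16.3-fold, the mitotic kinase Plk1 14.5-fold and the ribonucleotide reductase subunit Rrm2 14.0-fold. Of 15 plasma cell genes 14 rose (camera adjusted p = 4.05e-07; adjusted p = 0.388 with an estimated correlation). Besides Prdm1 they included Jchain (listed as Igj), which joins IgM and IgA subunits, from 56.2 ± 28.8 to 1214 ± 57.9 FPKM. Derl3, of the endoplasmic reticulum, was 22.1-fold and the transcription factor Xbp1 9.69-fold higher. Sdc1, the plasma cell surface marker CD138, was 3.61 ± 0.211 in resting and 3.66 ± 2.13 FPKM in activated cells (limma adjusted p = 0.877). All 18 genes of the unfolded protein response and secretion rose (camera adjusted p = 1.61e-07; adjusted p = 0.388 with an estimated correlation). The largest changes were those of Sdf2l1 (8.95-fold), Manf (8.51-fold), the chaperone Hsp90b1 (7.31-fold) and the disulfide isomerase Pdia6 (6.25-fold).

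All 13 tested genes of cholesterol synthesis rose (camera adjusted p = 1.02e-08; adjusted p = 0.342 with an estimated correlation). Fdps rose from 2.92 ± 0.149 to 42.2 ± 0.901 FPKM and the squalene epoxidase gene Sqle from 5.26 ± 0.789 to 67.7 ± 2.39 FPKM, and Idi1 was 9.95-fold and the sterol sensor gene Insig1 8.68-fold higher. In the list of one-carbon, serine and nucleotide synthesis 14 of 15 genes rose (camera adjusted p = 4.05e-07; adjusted p = 0.388 with an estimated correlation), led by the amino acid carrier Slc7a5 (15.1-fold) and the serine synthesis gene Psat1 (14.3-fold). The mitochondrial folate enzymes Mthfd2 and Shmt2 rose 8.99-fold and 6.92-fold. All 12 ribosome biogenesis genes rose (camera adjusted p = 0.000141; adjusted p = 0.388 with an estimated correlation), with Npm1 3.65-fold, Ncl 3.31-fold, Nop58 3.18-fold and Nolc1 2.62-fold higher. Of 12 glycolysis genes 9 rose and 3 did not pass (camera adjusted p = 0.00109; adjusted p = 0.480 with an estimated correlation). The fry adjusted p of this list was 0.0704. Pgk1 was 4.95-fold, Tpi1 4.74-fold, Pkm 4.40-fold and Pgam1 4.26-fold higher. The glucose carrier gene Slc2a1 had 16.6 ± 0.240 FPKM in resting and 12.7 ± 6.08 FPKM in activated cells (limma adjusted p = 0.243). Gapdh, which has many pseudogene copies, was listed at 0.624 ± 0.124 and 4.42 ± 0.874 FPKM, so that its level is uncertain. Of 9 class switching genes 7 rose (camera adjusted p = 0.00127; adjusted p = 0.342 with an estimated correlation), among them Batf, from 11.9 ± 0.460 to 90.2 ± 19.3 FPKM, Exo1 (5.02-fold) and Apex1 (3.97-fold).

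Of 19 genes of mature B cell identity 17 fell and 2 did not pass (camera adjusted p = 1.01e-06; adjusted p = 0.388 with an estimated correlation). Besides Cr2 these were led by Fcer2a, the low-affinity IgE receptor CD23, from 338.7 ± 2.14 to 56.9 ± 22.5 FPKM, and by Bcl6 and Blk. Pax5, the factor that maintains B cell identity, fell by 1.40 ± 0.172 (SE) on the log2 scale, from 94.8 ± 1.45 to 35.2 ± 0.339 FPKM. Of 17 genes of quiescence and homing 14 fell (camera adjusted p = 1.99e-05; adjusted p = 0.342 with an estimated correlation). The receptor for lymphoid egress S1pr1 fell from 127.7 ± 2.63 to 9.57 ± 0.603 FPKM, Klf2 from 180.2 ± 22.5 to 23.3 ± 3.18 FPKM and Tsc22d3 from 198.9 ± 94.3 to 17.5 ± 1.66 FPKM.

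The activation surface and NF-kB lists moved both ways. Of 14 surface genes 5 rose and 5 fell (camera adjusted p = 0.651; adjusted p = 0.765 with an estimated correlation). The interleukin-2 receptor chain Il2ra rose 13.3-fold, Cd80 4.66-fold, Tnfrsf13b 3.39-fold, Cd44 2.22-fold and Cd69 1.82-fold, while Cd38, Slamf1, Tlr4, Cd40 and Tnfrsf1b fell. Tlr4, the receptor that senses LPS, had 10.3 ± 0.119 FPKM in resting and 4.38 ± 0.215 FPKM in activated cells. Of 17 NF-kB genes 7 rose and 4 fell (camera adjusted p = 0.492; adjusted p = 0.736 with an estimated correlation). The cytokine genes Il10 and Il6 rose 11.8-fold and 9.43-fold and Ebi3 3.82-fold, and Lta, Birc3, Tnf and Rel fell. In the interferon list 2 of 10 genes rose, Isg15 (6.10-fold) and Ifit1 (2.76-fold), and 8 did not pass; its median was -0.248 and its mean -0.0532 on the log2 scale (camera adjusted p = 0.869, direction down; adjusted p = 0.959 with an estimated correlation). The direction of fry for this list was up (adjusted p = 0.818). The activated samples differed here, with a median log2 ratio of replicate 1 over 2 of 0.983: the list was called down without activated replicate 1 (camera adjusted p = 0.0445) and pointed up without replicate 2 (camera adjusted p = 0.0778), and Mx1 and Usp18 were called lower and higher in these settings. Adjusted over the list alone, the counts of all lists were as over all genes except 6 rises in the surface list, 8 rises and 5 falls in the NF-kB list, 18 falls in the B cell identity list, 8 rises in the class switching list and 5 falls in the myeloid list.

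**Figure D1:**
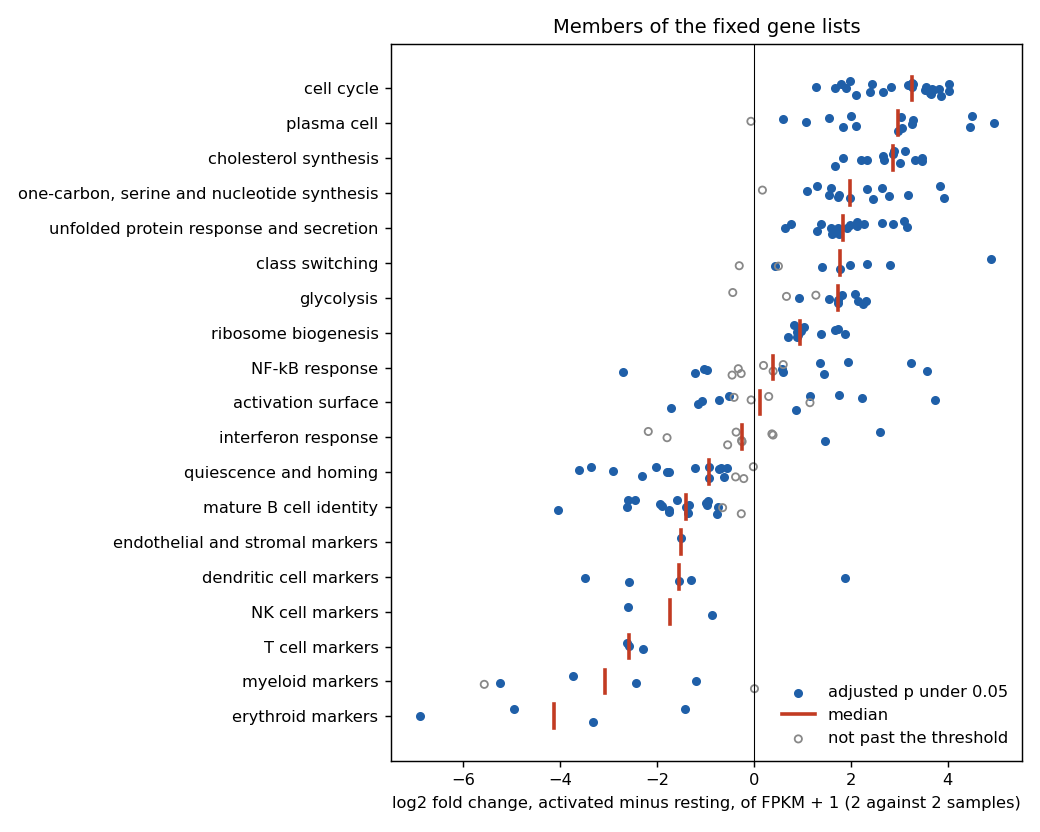
Log2 fold change (activated minus resting, FPKM + 1, 2 against 2 samples) of the tested members of each fixed list, 1 point per gene, filled where the limma adjusted p was under 0.05, with the list's median as a bar. The 24 cell cycle genes all lie above 0, 17 of the 19 mature B cell identity genes are filled and below 0, and the NF-kB and activation surface lists spread to both sides.

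Many transcripts of other cell types were lower in the activated than in the resting samples, beside the falls of the B cell identity and quiescence lists. Of 21 tested markers of other cell types 18 fell, 1 rose and 2 did not pass. A marker absent from activated cells was tested only where the resting samples reached the filter. Falls were therefore favoured in advance, also in the list tests of these markers. Some that fell were still present in activated cells, such as Pecam1 (21.3 ± 5.57 FPKM) and Fcgr3 (7.46 ± 2.40 FPKM). C1qa, C1qb and C1qc, complement genes of tissue macrophages, had 85.2 to 112.0 FPKM in the resting samples; C1qa and C1qb were listed at 0 in both activated samples and C1qc at 0 and 0.111. The adhesion gene Vcam1 had 59.6 ± 4.80 FPKM and the iron exporter gene Slc40a1 58.4 ± 6.58 FPKM in resting cells, against 0.0321 ± 0.0237 and 0.0123 ± 0.0174 FPKM in activated cells. Tyrobp, an adaptor of myeloid and NK cell receptors, fell from 86.0 ± 36.5 to 0.624 ± 0.538 FPKM.

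Of 6 tested myeloid markers 4 fell (camera adjusted p = 0.00127; adjusted p = 0.342 with an estimated correlation), namely Csf1r, Adgre1, Cd14 and Fcgr3. Without resting replicate 1 or 2 the camera adjusted p of the myeloid list was 0.0316 and 0.133. Csf1r, Adgre1 and Cd14 were then no longer tested, since only the remaining resting sample reached the filter, but in resting replicate 1 they had 36.1, 14.1 and 5.67 FPKM, against means of 0.0626, 0.246 and 0.171 FPKM in activated cells. Of 5 dendritic cell markers 4 fell and Flt3 rose 3.69-fold (camera adjusted p = 0.0237; adjusted p = 0.388 with an estimated correlation). All 3 tested T cell markers, Cd4, Cd8a and Lck, fell (camera adjusted p = 0.00365; adjusted p = 0.342 with an estimated correlation). The other 7 members were under the filter, and in resting replicate 1 the CD3 genes Cd3e, Cd3d and Cd3g, of the T cell receptor complex, had 0.135, 0.0491 and 0.0668 FPKM, where Cd4 had 5.48 and Cd8a 4.21 FPKM. The NK cell markers Klrd1 and Prf1 and the endothelial marker Pecam1, which leukocytes also express, fell, with no list test on so few genes. All 4 tested erythroid markers fell (camera adjusted p = 0.00682; adjusted p = 0.388 with an estimated correlation).

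The resting samples differed from each other in these transcripts. Hemoglobin Hbb-b1 had 393.5 FPKM in resting replicate 1 and 2324 in replicate 2, and Beta-s, a symbol for another beta globin gene, 950.9 and 6623. With all samples Hbb-b1 fell by 6.89 ± 1.10 (SE) on the log2 scale (limma adjusted p = 0.0148) and Beta-s by 9.95 ± 1.17 (limma adjusted p = 0.00806). Without resting replicate 1 or 2 the limma adjusted p was 0.000447 and 0.00328 for Hbb-b1 and 6.9e-05 and 0.000175 for Beta-s. Without activated replicate 1 or 2, where the spread came from the differing resting samples alone, it was 0.101 and 0.127 for Hbb-b1, with log2 differences of -7.515 and -6.26, and 0.0755 and 0.0891 for Beta-s, with -10.43 and -9.47. The near-identical globin genes share reads, so that their separate levels are uncertain. Lyz2, a lysozyme of macrophages and neutrophils, had 57.0 and 363.3 FPKM in the resting samples (limma adjusted p = 0.0657).

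**Figure D2:**
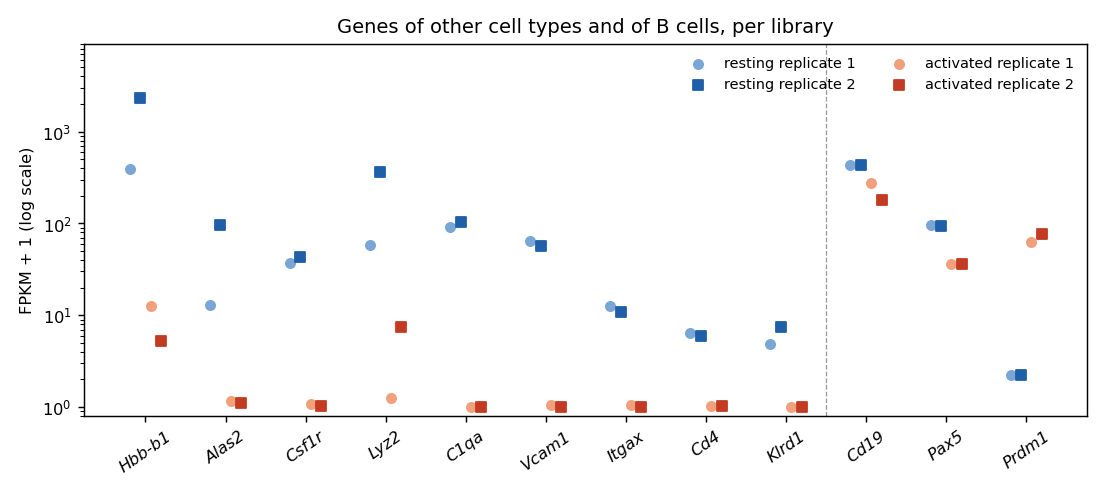
FPKM + 1 on a log axis for genes of other cell types (left of the dashed line) and of B cells (right), 1 point per library, circles for replicate 1 and squares for replicate 2. Hbb-b1 lies at 393.5 and 2324 FPKM in the resting libraries, C1qa is listed at 0 in both activated libraries, and Prdm1 is 1.23 and 1.26 FPKM in resting against 61.3 and 75.8 FPKM in activated libraries.

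The second comparison asks which open regions of activated B cells act as enhancers in the plasmid assay and what marks they carry. Of 55126 FAIRE peaks 11872 (21.5%, 95% interval 20.9 to 22.3) overlapped a STARR peak, against a mean of 0.43% and a highest value of 0.60% in 1000 circular shifts (permutation test, one-sided, p = 0.001, the smallest it can give). The plasmid library was made from FAIRE DNA, so an excess over shifts across the chromosome was built into the assay and says nothing of enhancer activity. From the side of the assay, 67.9% of 17381 STARR peaks lay in a FAIRE peak (65.1 to 71.0). STARR peaks in FAIRE lay mostly near H3K4me3. Of the 11806 such peaks 7610 (64.5%) lay within 1 kb of an H3K4me3 peak, a mark of active promoters, and 4196 (35.5%) lay farther away. H3K27ac, a mark of active enhancers and promoters, was present at 89.6% of the former (88.4 to 90.7) and 37.7% of the latter (35.2 to 39.9).

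FAIRE peaks with a STARR peak carried both marks more often than those without. H3K27ac overlapped 71.6% of 11872 FAIRE peaks with a STARR peak (69.1 to 74.0) and 43.3% of 43254 without (41.5 to 45.4), an odds ratio of 3.29 (2.90 to 3.62; Fisher's exact test, two-sided, p at or under 1e-300). H3K4me3 overlapped 60.3% (57.3 to 63.4) and 33.5% (31.8 to 35.6), an odds ratio of 3.01 (2.71 to 3.29; p at or under 1e-300). Over the 4 peak tests the Benjamini-Hochberg adjusted p was at or under 2e-300 for both marks and 0.001 for the overlaps with FAIRE peaks and super-enhancers. Fisher's exact test treats neighbouring peaks as independent, which they are not, so its p-values are too small. More than 1 kb from H3K4me3, H3K27ac was found at 38.2% of FAIRE peaks with a STARR peak and 22.1% of those without, an odds ratio of 2.18 (1.90 to 2.43; Fisher's exact test, p = 5.64e-104). Both odds ratios turned when FAIRE peaks were compared within 10 equal parts of the deposited FAIRE list, an alternative chosen after seeing the data: that of H3K27ac was 0.811 (0.737 to 0.879) and that of H3K4me3 0.684 (0.617 to 0.756). The share of FAIRE peaks with a STARR peak was 79.4% in the first of the 10 parts and 3.86% in the last, and the meaning of the list order is not stated.

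**Figure D3:**
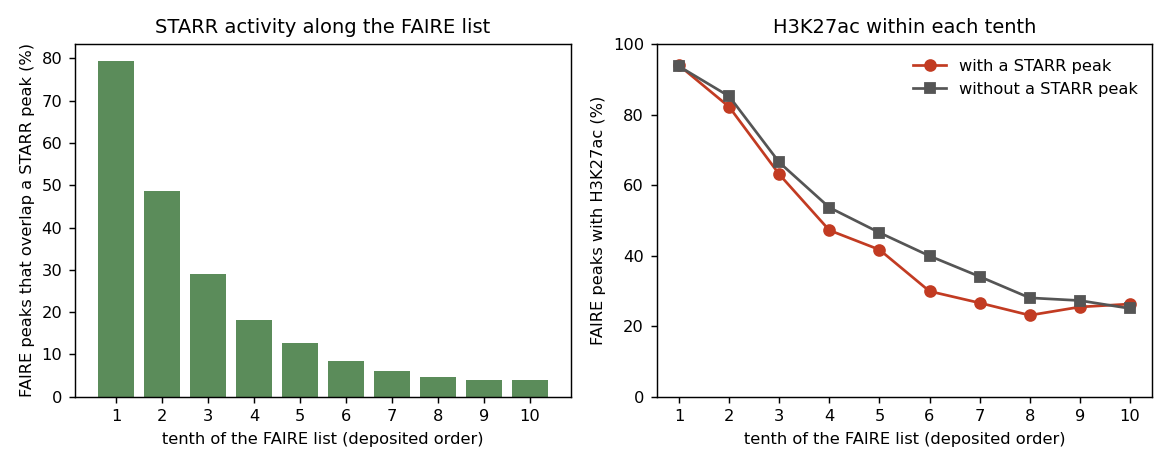
Left, the share (%) of FAIRE peaks that overlap a STARR peak in each of 10 equal parts of the FAIRE list in its deposited order; right, the share (%) with H3K27ac among peaks with (circles) and without (squares) a STARR peak in the same parts. The first share falls from 79.4% to 3.86%. In part 6, which has the lowest odds ratio, 29.9% of peaks with and 39.9% of peaks without a STARR peak carried H3K27ac. Parts 1 (93.93% with, 93.65% without) and 10 (26.29% with, 25.04% without) went the other way.

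The third comparison asks whether super-enhancers hold regions active in the assay. Of 48 super-enhancers 45 (93.8%) held a STARR peak, against a mean of 6.6% and a highest value of 22.9% in 1000 circular shifts of the STARR peaks (permutation test, one-sided, p = 0.001, the smallest it can give). As for FAIRE peaks, an excess over these shifts was built in, since the library came from open DNA. In windows of the same widths centred on other H3K27ac peaks, chosen after seeing the data, the mean was 44.8% and the highest value 66.7%, but the median width was 1037 bp for H3K27ac peaks and 10358 bp for super-enhancers, so these windows can hold much DNA without the mark. Of the 886 other H3K27ac peaks at least as wide as the narrowest super-enhancer 663 held a STARR peak. Most STARR peaks, 7, lay in the super-enhancer on chromosome 7 from 29156120 to 29171855 (mm9), which overlaps the loci of Med29, Plekhg2 and Zfp36. The one on chromosome 5 from 124925450 to 124934275, at Rilpl2 and Snrnp35, and the one on chromosome 6 from 129178501 to 129188735 held 6 each. The one on chromosome 8 from 87498749 to 87510645, at the gene of the AP-1 factor Junb, held 5. Another 5 held 4 each, among them one at Pax5 (chromosome 4 from 44714665 to 44727609) and one at the secretory pathway gene Serp1 and Eif2a (chromosome 3 from 58319916 to 58330443). The 3 without a STARR peak overlapped Chst3, Laptm5 and Ly6e. STARR peaks were found at 0.234 per kb of super-enhancer (0.201 to 0.277) and 0.209 per kb (0.193 to 0.225) of these 886 peaks. The RNA table gives loci without exons, so the position within a gene is not given.

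The fourth comparison asks how genes connected to these enhancers by Hi-C were expressed. Linked genes were more highly expressed than others: the 7956 linked genes had a median of 12.7 FPKM in activated cells and the 15856 other genes a median of 0 FPKM, a difference of 3.76 in median log2(FPKM + 1) (3.729 to 3.799; permutation test, two-sided, p = 1e-05, the smallest it can give). Part of this difference is built in, since per the series design the enhancers were connected to promoters found active by RNA-seq, and a link here also needed H3K4me3 at the gene. Among genes with H3K4me3 at an end of the locus, a background chosen after seeing the data, the difference was 2.80 (2.58 to 2.98), and among genes expressed in activated cells 1.40 (1.20 to 1.61). Linked genes had a median of 3 enhancers and at most 25, and 75.5% of STARR peaks in FAIRE were linked to a gene. These linked regions are called enhancers only for their activity in the assay: 72.5% of them lay within 1 kb of H3K4me3, and 63.6% of contacts had H3K4me3 in both anchors. The median distance between anchors was 371.1 kb, and the enhancers of a gene lay a median of 987.7 kb from its end.

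B9d2 on chromosome 7 had the most linked enhancers, 25, followed by the histone gene Hist1h4k (24), Trim27 (23) and the cell cycle inhibitor gene Cdkn1b (22). The median distance to their enhancers was 1910.1, 1792.2, 2256.5 and 5696.1 kb. Many contacts rested on few reads, with a median count of 7 and a lowest of 5, so the numbers of linked enhancers are uncertain. Atf6, a sensor of the unfolded protein response, had 21 and rose from 14.7 to 52.8 FPKM (limma adjusted p = 0.000264). Stx5a, Wdr46 and Hist1h2ag also had 21, Pias4 20 and Cnn2 19. Hist1h4k, Trim27 and Hist1h2ag lie near each other on chromosome 13, so their links are not independent. Of these, Trim27, Wdr46, Hist1h4k and Atf6 were higher and Cdkn1b and Cnn2 lower in activated cells, while B9d2, Stx5a and Pias4 did not pass and Hist1h2ag was below the filter. Histone genes have near-identical copies, so that their values are uncertain. Among list members, Nfkbie had 19 linked enhancers, Manf 15, Syvn1 12, and Apex1, Cd79a, Impdh2 and Cdc6 11 each. Prdm1 had 9, at a median distance of 229.9 kb, and Pax5 6. No marker of T, myeloid, NK, erythroid or endothelial and stromal cells was linked, and of the dendritic cell markers Flt3 was, with 4 enhancers. A link needed H3K4me3 at the gene and a promoter active by RNA-seq, so genes silent in activated cells could hardly be linked.

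Linked genes were more often induced than others expressed in activated cells. Of 7232 linked genes 2299 (31.8%) were higher in activated cells and 1487 (20.6%) lower. Of 2917 other genes 767 (26.3%) were higher and 711 (24.4%) lower. The odds ratio of induction was 1.31 (1.17 to 1.48; Fisher's exact test, two-sided, p = 4.42e-08). Links rested on enhancers, H3K4me3 and promoter activity of activated cells, so an excess of induced genes was favoured in advance. Matched on the level in activated cells, over the same 7232 linked and 2917 other genes, the odds ratio was 0.933 (0.808 to 1.08; Cochran-Mantel-Haenszel chi-square test, p = 0.218). The activated level is part of the outcome, however, so this matching can remove induction itself. Matched on the mean level of all samples or on the resting level, both chosen after seeing the data, the odds ratio was 1.43 (1.24 to 1.66; chi-square p = 1.26e-11) and 1.99 (1.71 to 2.32; chi-square p = 1.84e-37). Matching on the resting level has the opposite bias. Across 7328 linked genes, which are not independent replicates, the number of enhancers and the log2 fold change had a Spearman rho of 0.0242 (permutation test, two-sided, p = 0.0382). The partial rho was -0.0225 given the activated level (permutation p = 0.0554), 0.0208 given the mean level (permutation p = 0.0742) and 0.0592 given the resting level (permutation p = 1e-05), and among genes with at least 2 enhancers rho was -0.0021 (permutation p = 0.872). With the 3 Hi-C tests adjusted together by Benjamini-Hochberg, p was 1.5e-05 for the level, 1.33e-07 for induction and 0.0382 for the number.

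**Figure D4:**
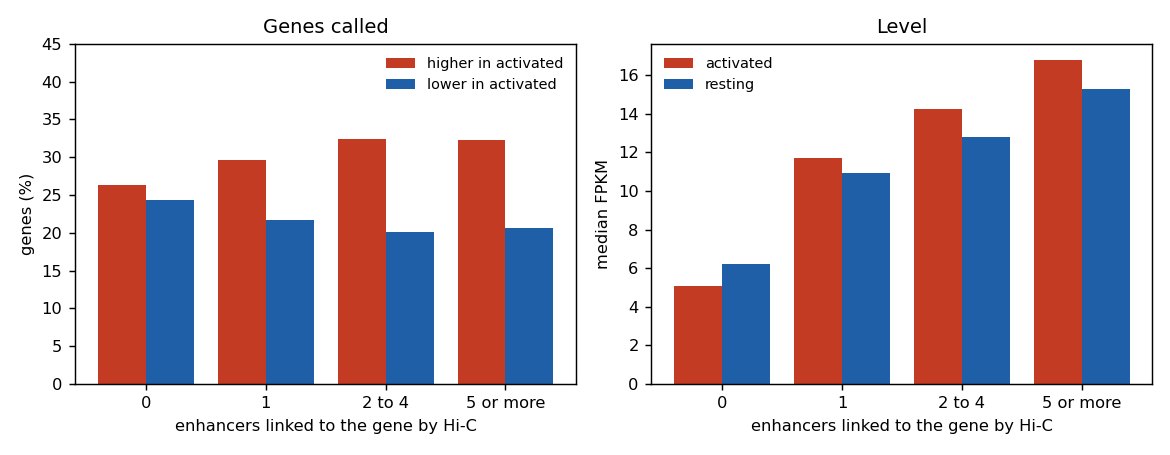
Left, the share (%) of genes expressed in activated cells that were called higher or lower in activated cells, by the number of enhancers linked by Hi-C; right, their median FPKM in activated and resting cells. The share called higher is 26.3% without a linked enhancer and 32.2% with 5 or more, and the median activated level 5.06 and 16.8 FPKM.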

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

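The test below on STARR peaks outside FAIRE peaks and the comparison within 10 equal parts of the FAIRE list were chosen after the data had been examined, whereas the comparison away from H3K4me3 was planned.

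Peaks that the comparisons of FAIRE peaks leave out overlapped H3K27ac more than shifted peaks did. Of the 5575 STARR peaks outside FAIRE peaks 743 (13.3%, 95% interval 11.8 to 15.4) overlapped an H3K27ac peak, against a mean of 1.63% and a highest value of 2.26% in 1000 circular shifts. The plasmid library was made from FAIRE DNA, so fragments of open regions missed by the FAIRE list would give such an excess in advance, and it says nothing of enhancer activity.

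H3K27ac was more frequent at FAIRE peaks with a STARR peak than at those without, with an odds ratio of 3.29. Promoters marked by H3K4me3 do not alone account for this, since the odds ratio was 2.18 (1.90 to 2.43) more than 1 kb from H3K4me3. The strength of the FAIRE peak may account for it: within 10 equal parts of the FAIRE list the excess was gone, and the odds ratio of 0.811 (0.737 to 0.879) lay below 1, where the prediction written before the test had been an interval that includes 1. Counting this result for the explanation was decided after it was seen, and the order of the list, whose meaning is not stated, is only a stand-in for strength. More than 1 kb from H3K4me3 the odds ratio within the 10 parts was 0.943, with an interval that includes 1 (0.852 to 1.03). A biological link between activity in the plasmid assay and the mark stays open, since a stronger FAIRE peak can itself reflect an active region and the plasmid library was made from FAIRE DNA.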

How the results depend on the processing

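The comparisons by list order, by mean and resting level, by H3K4me3 at the gene, by any gene end and by windows on other H3K27ac peaks, and quantile normalization for the lists, were chosen after seeing the data, and the other alternatives were planned.

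Genes called numbered 5910, and 2964 to 5693 with a replicate left out (higher 1735 to 2859, lower 1191 to 2834). Without a resting library 580 of the lower genes were no longer tested, and the lone sample of a group was assumed to vary like the others. At an adjusted p under 0.01, 3714 genes were called (1935 higher, 1779 lower), and at 2-fold or more 2842 (1525 higher, 1317 lower). Filters, pseudocounts and quantile normalization moved the count by less than 1.5 times. Of 17 lists tested camera called 14, fry 13 (glycolysis lost, adjusted p = 0.0704) and camera with an estimated correlation 0. The estimated correlation setting rests on the residual degrees of freedom of 2 against 2 samples and had little power. With a replicate left out camera called 10 to 15, but without a resting replicate only 14 lists could be tested, since the T cell, dendritic cell and erythroid lists had too few genes.

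With the replicate number as a replicate block 6281 genes were called, and the limma adjusted p was 0.130 for Hbb-b1 and 0.0835 for Beta-s. The deviations of same-numbered samples had an r of 0.124 across genes, and the labels do not say that the numbers pair the samples.

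Within 10 parts of the FAIRE list the odds ratio was 0.811 for H3K27ac and 0.684 for H3K4me3. Away from H3K4me3 that of H3K27ac was 0.943 within these parts, with an interval that includes 1 (0.852 to 1.03). Matched on the activated level, which is part of the outcome, the odds ratio of induction was 0.933, and 0.935 among genes with H3K4me3, but 1.43 matched on the mean level. The rho of enhancer number was -0.0225 given the activated level, 0.0208 given the mean level and -0.0021 with at least 2 enhancers. The cause was not tested beyond these settings.

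Values under alternatives were compared for 238 genes, the named genes and other tested list members. Of 2298 values 2149 kept direction and side of the threshold. Without a change of sign 103 lost the call and 32 gained one, and 14 changed sign. A gene under the filter in a setting has no value there, and without resting replicate 1 only 219 genes had one. Nfkb1 was -0.062 on the log2 scale under quantile normalization and Itgam -0.001 with a pseudocount of 5. With a replicate left out, Cd86 ranged from -0.91 to 0.10, Cd83 from -0.006 to 0.62, Icam1 from -0.14 to 0.026, Sdc1 from -0.54 to 0.42, Foxo3 from -0.041 to 0.019, Slc2a1 from -0.90 to 0.033, Usp18 from -0.74 to 1.53, Irf7 from -0.34 to 1.08, Mx1 from -1.46 to 0.98 and Itgam from -0.26 to 0.28. None of these was called with all samples. Mx1 and Usp18 were called lower without activated replicate 1 and higher without activated replicate 2, Cd86 lower without the former, and Irf7 higher and Slc2a1 and Sdc1 lower without the latter. The interferon list was called down without activated replicate 1 (camera adjusted p = 0.0445) and turned up without activated replicate 2 (0.0778) and under fry (0.818). It was not called without a resting replicate (up to 0.807). The NF-kB list turned down without activated replicate 1 (0.976), and its lowest value with a replicate left out was 0.472.

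Count-based tests, the higher-scored part of the peak lists and matching on width and score were not run, because the tables hold no read counts per gene and the lists no score. Read depth is unknown, so its limit on low genes cannot be given.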

Other observations

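The tests on markers of other cell types, the values on peak widths and list order and those on differences between activated samples were chosen after the results were seen, as was the pattern at super-enhancers, whose 3 tests were written down before they were run; that the third decides nothing was judged afterwards.

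The activated samples differed in interferon genes. The median log2 ratio of activated replicate 1 over replicate 2 was 0.98 over the interferon list, with Mx1 at 17.1 and 2.32 FPKM, Usp18 at 16.4 and 2.61 FPKM and Irf7 at 39.3 and 14.0 FPKM. The median ratio was -0.92 over glycolysis genes and -0.74 over cell cycle genes. With 1 sample on each side these differences have no test.

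Genes whose loci overlap super-enhancers of activated cells were often lower in activated than in resting cells. Super-enhancers that overlap no listed gene do not enter, such as the first listed (chromosome 12 from 114477204 to 114496063). Genes near a super-enhancer but not overlapping it do not enter either. Of 48 tested genes whose locus overlaps a super-enhancer 9 rose and 21 fell, with a median log2 fold change of -0.41 against 0.03 for other genes (permutation test, two-sided, p = 0.00344). Their median activated level was 46.8 FPKM against 10.5. Among the lower ones were Pax5 and Cd79b, of the B cell receptor, and among the higher ones Rilpl2, Serp1 and Eif2a; these genes were chosen after their values were seen.

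That fall was set against 3 explanations. The values argue against expression level: the lowest median of 10000 gene sets matched on mean level was -0.38, above the -0.41 of these genes (p = 0.0001 by permutation, the smallest it can give), and 95% of the sets lay between -0.07 and 0.52. Several of the 48 genes share a super-enhancer, such as Pfn1, Rnf167 and Slc25a11, while the random sets drew single genes. The permutation p-values for these genes may therefore be too small. Without resting replicate 2 the median less that of the other genes was -0.57, against -0.44 with all samples. Leaving out the B cell identity and quiescence lists (-0.41) decides nothing, since they held only 2 of the 48 genes, and B cell identity genes outside the lists stay open. A candidate explanation, as a hypothesis, is that these super-enhancers mark genes already active in resting B cells; resting super-enhancers were not analysed here, and RNA of other cells in the resting samples stays open.

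Markers of other cell types were lower in activated cells. Of 21 tested markers 85.7% fell. Many of them passed the filter only through the resting samples, so that a fall was nearly fixed in advance. The share therefore cannot decide whether other cells in the resting samples were lost in culture. CD43 selection removes T cells and many myeloid cells. T cells are argued against as the source of Cd4, Cd8a and Lck in resting replicate 1, where the median of Cd3e, Cd3d and Cd3g was 0.0668 FPKM and Cd4 had 5.48, while the CD3 median was 1.29 in replicate 2. The resting libraries differed, with a median log2 ratio of replicate 2 over 1 of 1.61 over erythroid, 1.07 over NK and 0.77 over T cell markers, and Beta-s at 6623, Hbb-b1 at 2324 and Lyz2 at 363.3 FPKM in replicate 2. The macrophage genes did not depend on that library, since without it the median log2 difference of C1qa, C1qb, C1qc, Vcam1, Slc40a1 and Csf1r was -6.19. Lower expression of these genes within B cells was not tested and stays open, and Flt3 and Pecam1 are also expressed by B cells.

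Nearly all STARR peaks had 1 of 2 widths that differ by 1 bp, the longer in 11566 peaks and the shorter in 5813. FAIRE peaks overlapped 77.3% of the longer and 49.3% of the shorter, an odds ratio of 0.287 (0.273 to 0.302). Of 10 equal parts of the list, the shorter peaks were absent from the first 6, made up 34.5% of part 7 and all of the last 3. Within these parts the odds ratio was 1.33 (1.02 to 1.70), decided by part 7. Among the first 20 STARR peaks listed 4 overlapped H3K27ac, but 68 of the first 100 did and 82.9% of the first of the 10 parts, the highest of all parts. Among FAIRE peaks these were 15 of the first 20 and 88 of the first 100.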
